A study of Homo sapiens with 6 samples.

How the data were processed

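Total RNA from cultures of H69, a small cell lung cancer cell line, and of H69M was measured on Affymetrix whole-transcript arrays, with 3 arrays of each line. Per the labels' protocols, RNA was extracted with a column kit, amplified, labelled with biotin by a sense-target method and hybridised. The deposited values are log2 values per probe set, and the submitters' processing notes name RMA and limma without versions. RMA as it is usually run corrects background, quantile normalizes the arrays to each other and summarises the probes of a probe set by median polish. Such values carry no detection call, and RMA compresses folds against dim genes, so a fold from a dim level can understate the change. The software that ran RMA and the genome build are not given in the sources used here. No array was left out, and nothing was normalized again for the main results.

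The table held 32321 probe sets on each of 6 arrays. The platform annotation gave 1 gene symbol to 19158 probe sets and several to 1388, and did not list 11775. Genes were named from the probe sets with 1 symbol, which covered 18404 genes. Of those probe sets, 19128 matched the reference gene table (assembly GRCh38.p14, used for names and for the order of neighbouring genes only) by Entrez ID, and 0 symbols had to be updated. For the 637 genes with more than 1 probe set, the probe set with the highest mean over the 6 arrays was used. The probe sets of 34 of these genes differed by more than 1 in log2 fold change.

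The comparison was H69M against H69, fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, trend off, two-sided) on the log2 values as deposited, with group as the only term. P-values were adjusted over the 18404 genes by the Benjamini-Hochberg method with a threshold of 0.05, and a second pair of counts also asked for a log2 fold change of at least 1. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 34 lists. Camera with an estimated correlation and fry were alternatives. Of 1074 list symbols, 957 were measured. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for annotation, for the tests of explanations and for plots.

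The lists and the rule for named genes were fixed before the data were examined. The rule took the 15 largest rises and the 15 largest falls among protein-coding genes past the threshold, with a mean in the higher group at or above the median of all genes and no overlap between the arrays of the groups. It added up to 4 members past the threshold with the largest change from each list, and 38 fixed genes, of which 34 were measured; the others are not analysed here.

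The alternatives were the replicate number as a block, each array centred on its median, quantile normalization applied again, the genes below the 25th percentile of level or below the median level left out, eBayes with trend, robust eBayes, array weights, other treatments of probe sets, and each array left out in turn. The labels do not say that the 3 replicates of a line were separate cultures, so the p-values measure the spread between these arrays, which may be technical. The number of arrays limits the precision. The median standard error of a log2 fold change was 0.075. The code was tested on simulated data: with 200 of 18404 genes changed in a simulated H69M against H69 comparison, limma recovered 12% of the genes changed by 0.25 in log2, 88% of those changed by 0.5 and 100% of those changed by 1, and 9 calls were false (5.66% of calls). Far fewer genes were changed there than the 44.2% that passed in the real comparison. The Benjamini-Hochberg cut-off depends on that share, so the recovered percentages do not give the sensitivity of the real comparison. A raised mesenchymal list was called by camera, and 0 of 26 lists that share no member with it were. The simulated genes varied independently of each other, whereas the estimated correlation in the real lists reached, for example, 0.517 for neuroendocrine genes. That check therefore does not give camera's error rate in the real comparison. In a shuffled gene order with a planted run of 40 genes shifted by -0.8, all 26 windows inside the run were found.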

Results

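Gene expression was compared between 2 human small cell lung cancer lines, H69 and H69M, with 3 arrays of each. H69 is a classic neuroendocrine line that grows as floating aggregates; the labels do not say how H69M was obtained. The array medians over all probe sets lay between 6.43 and 6.48 on the log2 scale. Arrays of the same line correlated across genes with a mean r of 0.995 to 0.997, and arrays of different lines with 0.939 to 0.950. The first principal component took 92.2% of the variance and separated the lines. H69M replicate 1 stood nearer to H69 (41.5) than H69M replicates 2 (51.5) and 3 (51.1).

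H69M differed from H69 in 8140 of 18404 genes, with rises that went much further than the falls. At limma's Benjamini-Hochberg adjusted p threshold of 0.05, 3866 genes were higher in H69M and 4274 were lower. At least 2-fold differences were found for 1024 genes higher and 500 lower. Rises of more than 4 in log2 were seen in 83 genes and falls of that size in 4. The arrays of the lines did not overlap in 10273 genes (55.8%, where chance gives 10%), and the median log2 fold change of all genes was -0.041. Leaving out the genes below the median level reduced the 2-fold counts to 483 higher and 323 lower.

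**Figure D1:**
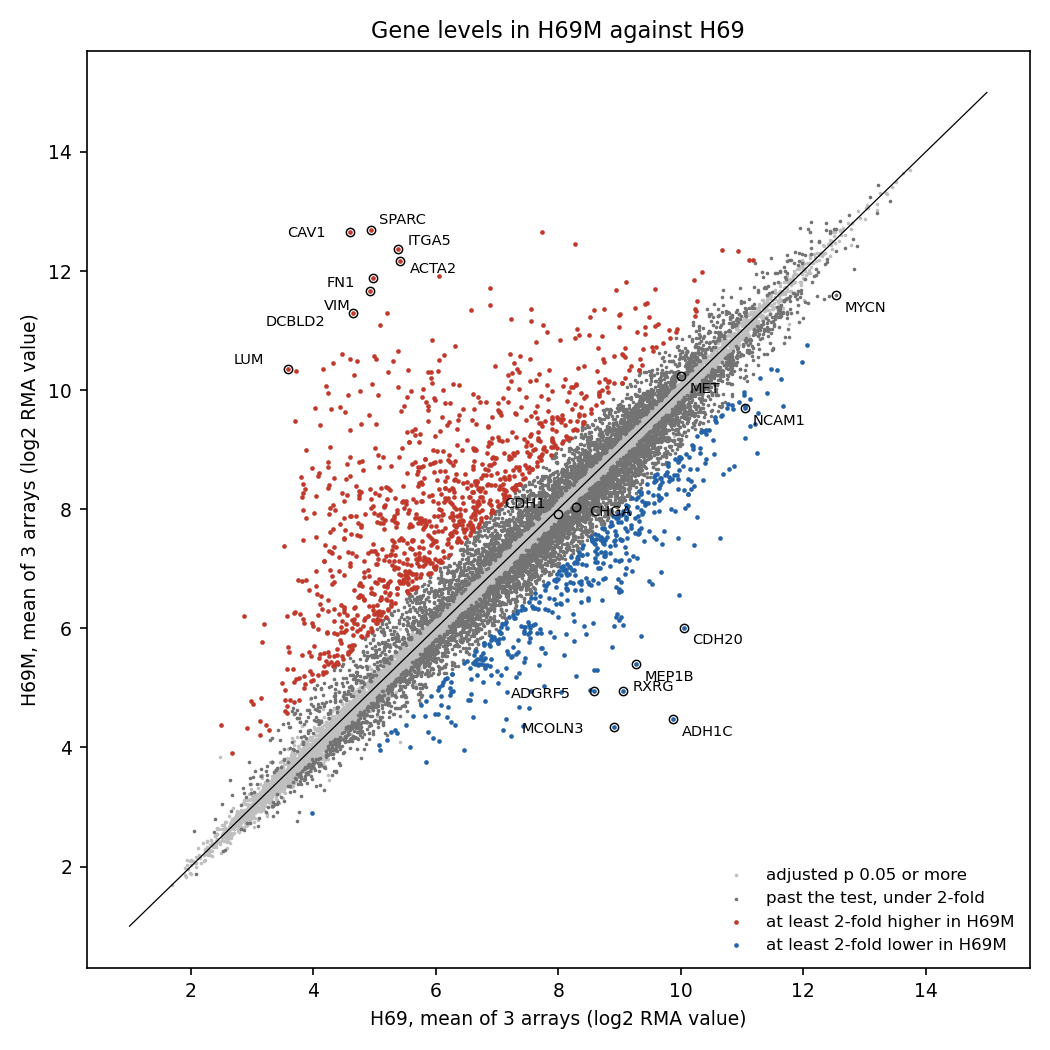
Mean log2 RMA value of each gene in H69M (vertical axis) against H69 (horizontal axis), each over 3 arrays; red and blue points are the 1024 genes at least 2-fold higher and the 500 at least 2-fold lower in H69M, dark grey points passed the test with a smaller change, and the line marks equal levels. CAV1, SPARC and ITGA5 moved from the dim end in H69 to above 12 in H69M, while MYCN stayed among the brightest genes in both.

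CAV1 had the largest rise of the genes that met the naming rule, followed by SPARC, ITGA5 and FN1. CAV1, the scaffold protein of caveolae (probe set 8135594), rose from 4.60 ± 0.14 in H69 to 12.65 ± 0.048 in H69M (log2, SD, n = 3), a 265-fold difference (limma, Benjamini-Hochberg adjusted p = 4.96e-09). The matricellular glycoprotein SPARC rose by 7.75 ± 0.095 (log2, SE), ITGA5, the alpha subunit of the fibronectin receptor, by 6.99 ± 0.097, and FN1, fibronectin itself, by 6.91 ± 0.085. LUM, a small matrix proteoglycan, rose by 6.78, ACTA2, smooth muscle actin, by 6.76, and the intermediate filament gene VIM by 6.74. The receptor gene DCBLD2 rose by 6.64, IL6ST, which encodes the shared receptor subunit gp130, by 6.60, and MME, the membrane protease neprilysin, by 6.20. FBN1 (fibrillin) rose by 6.13, the endocytic adaptor DAB2 by 6.13, TGFBI by 6.09, FSTL1 by 6.01 and MYOF, a membrane repair protein, by 5.94. The highest limma adjusted p among these 15 genes was 2.53e-07, for LUM.

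The falls were smaller. ADH1C, an alcohol dehydrogenase, fell from 9.88 ± 0.13 to 4.48 ± 0.093 (log2, SD, n = 3), which made it 42.4-fold lower in H69M (limma, Benjamini-Hochberg adjusted p = 1.45e-08). The lysosomal channel gene MCOLN3 had a log2 fold change of -4.55, the retinoid receptor gene RXRG -4.11 and the cadherin gene CDH20 -4.04. MEP1B, the beta subunit of the protease meprin, stood at -3.88, the adhesion receptor gene ADGRF5 at -3.64, and PTPRM, a receptor tyrosine phosphatase, at -3.54. Falls were also measured for POF1B (-3.48), EYS (-3.40), PARM1 (-3.34) and CLIC6 (-3.27). The neuronal vesicle gene NSG2 had -3.21, ENPP2, which encodes autotaxin, -3.12, PIP5K1B, a phosphoinositide kinase, -3.11, and SNAP91, a synaptic clathrin adaptor, -3.11. The highest limma adjusted p of the 15 was 3.93e-06, for EYS.

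Mesenchymal and matrix genes rose together. Of 32 measured mesenchymal genes, 26 rose and 0 fell, with a median log2 fold change of 2.75 (camera adjusted p = 4.02e-18; adjusted p = 0.115 with an estimated correlation). SPARC, FN1, ACTA2 and VIM led this list. The transcription factor genes ZEB1 (2.05 ± 0.067, log2, SE) and ZEB2 (2.68 ± 0.16) rose, as did TWIST1 (0.36 ± 0.061), N-cadherin (CDH2, 1.69 ± 0.070) and the hyaluronan receptor CD44 (1.63 ± 0.072). SNAI1 had a log2 fold change of 0.078 that did not pass. SNAI2 was already among the brightest genes in H69 (11.98 ± 0.032) and its fold change of 0.22 had a limma Benjamini-Hochberg adjusted p = 0.0632, which became 0.0101 without H69M replicate 3 and lay between 0.0217 and 0.0443 under 5 other alternatives, such as centred arrays (0.0375). Of 39 extracellular matrix genes, 33 rose and 1 fell (median 1.72, camera adjusted p = 4.02e-18; adjusted p = 0.115 with an estimated correlation), led by SPARC, FN1, LUM and FBN1. Of 34 integrin and focal adhesion genes, 26 rose and 1 fell (median 1.30, camera adjusted p = 2.19e-13; adjusted p = 0.122 with an estimated correlation), among them CAV1, ITGA5, LPP (4.39) and LAYN (4.37). Of 18 fibroblast markers, 13 rose and 1 fell (median 2.01, camera adjusted p = 6.12e-07, or 0.156 with an estimated correlation). LUM, PRRX1 (5.57), COL1A1 (4.83) and FAP (3.92) were in front. Most of these markers are also in the mesenchymal or matrix lists, so their rise is largely the same result. Outside those lists FAP, PDGFRB (3.15) and PDGFRA (1.58) rose, while DPT, TCF21 and MEOX2 did not pass.

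Epithelial genes went down on balance, but E-cadherin did not pass the test. Of 33 epithelial genes, 20 fell and 3 rose (median -0.56, camera adjusted p = 0.005; adjusted p = 0.558 with an estimated correlation). Falls were measured for RAB25, a vesicle GTPase of epithelial cells (-1.94), the transcription factor gene ELF3 (-1.55) and EPCAM (-0.57). E-cadherin, CDH1, stood at 7.99 ± 0.15 in H69 and 7.92 ± 0.36 in H69M (log2, SD, n = 3), a difference of -0.070 that did not pass (limma, Benjamini-Hochberg adjusted p = 0.773). Against the direction of the list, P-cadherin (CDH3) rose by 3.85 and the keratin gene KRT18 was 4.01-fold higher.

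**Figure D2:**
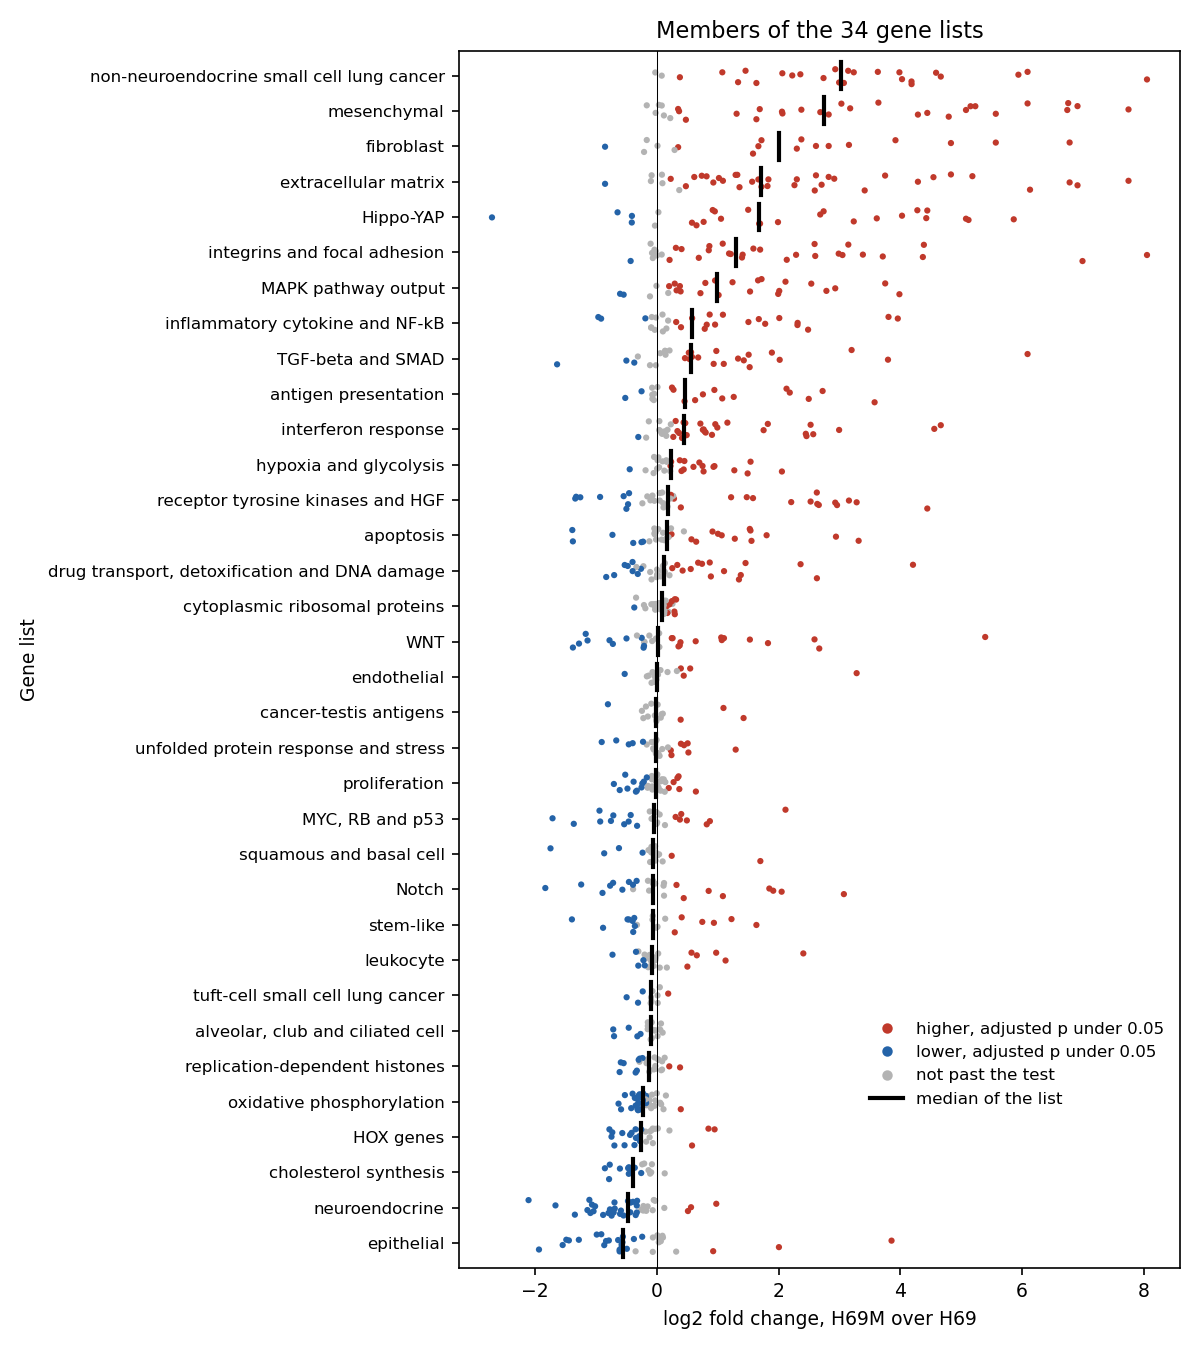
Log2 fold change, H69M over H69, of each measured member of the 34 gene lists (horizontal axis), with the lists ordered by their median (black bar); red and blue points passed limma's adjusted p threshold of 0.05 as higher or lower, and grey points did not. The medians run from 3.03 in the non-neuroendocrine small cell lung cancer list to -0.56 in the epithelial list.

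Most neuroendocrine genes fell, by a small amount at the median, and most genes of non-neuroendocrine small cell lung cancer rose, by a larger one. Of 39 neuroendocrine genes, 27 fell and 3 rose (median -0.48, camera adjusted p = 2.68e-06; adjusted p = 0.516 with an estimated correlation). Those that fell included the synaptotagmin gene SYT4 (-2.11), SEZ6 (-1.67), the adhesion molecule NCAM1 (-1.35), CHGB, a secretory granule protein (-1.14), and synaptophysin, SYP (-0.80). INSM1, a neuroendocrine transcription factor, had a log2 fold change of -0.33 (limma, Benjamini-Hochberg adjusted p = 0.0212), and this call was lost without H69 replicate 2 (0.0704), H69 replicate 3 (0.0506), H69M replicate 2 (0.066) or H69M replicate 3 (0.0584). Chromogranin A, CHGA, had a fold change of -0.26 that did not pass (limma adjusted p = 0.10) but did without H69M replicate 1 (-0.37, limma adjusted p = 0.016). Of 26 genes of the non-neuroendocrine list, 24 rose and 0 fell (median 3.03, camera adjusted p = 4.02e-18; adjusted p = 0.122 with an estimated correlation). CAV1, TGFBI, MYOF and the interferon-induced IFITM3 (4.66) led it, and YAP1, the effector of Hippo signalling, rose by 3.23 ± 0.16 (log2, SE). REST, a repressor of neuronal genes, rose by 3.07 ± 0.15. The tuft-cell list had 1 gene higher and 3 lower of 11 (camera adjusted p = 0.457), and POU2F3 had a fold change of -0.098 that did not pass.

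**Figure D3:**
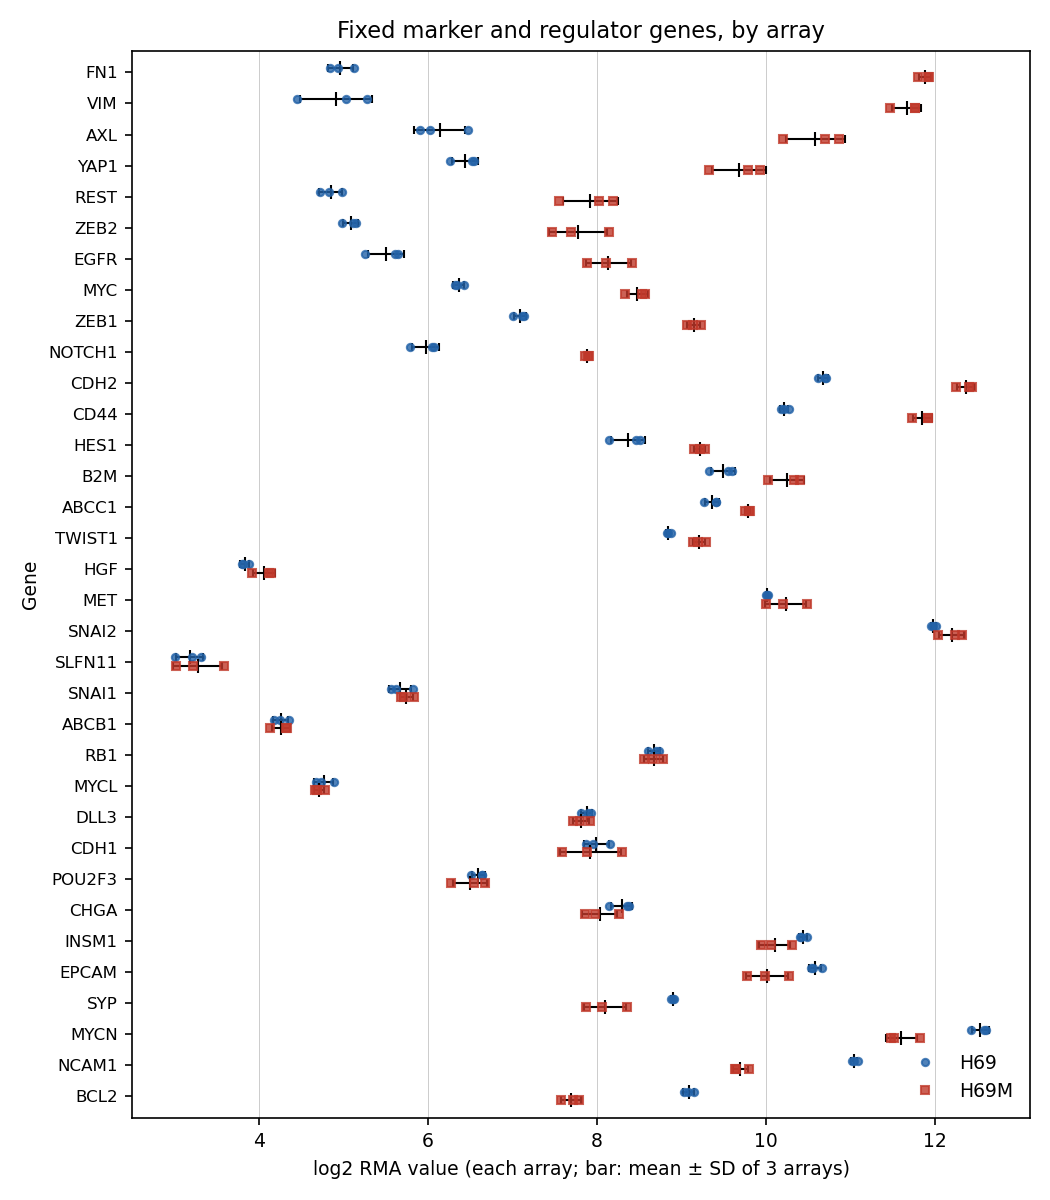
Log2 RMA value of 34 genes fixed in advance (horizontal axis), with each of the 3 H69 arrays as a blue circle and each of the 3 H69M arrays as a red square; black bars give the mean and SD of each line, and genes are ordered by log2 fold change. FN1, VIM, AXL and YAP1 stand apart without overlap, whereas the arrays of MET, CDH1 and RB1 overlap between the lines.

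Notch, MYC and cell cycle genes gave mixed pictures. In the Notch list 8 of 26 genes rose and 9 fell, with a median of -0.068, a mean of 0.15 and a camera adjusted p = 0.921. The receptor genes NOTCH1 (1.91) and NOTCH3 (1.85), the ligand gene JAG1 (2.05) and the target HES1 (0.85) rose. Other members, named after their values were seen, fell: the targets HEY2 (-1.84), HEY1 (-0.90) and NRARP (-0.46) and the ligand genes DLL1 (-1.25), DLL4 (-0.77) and JAG2 (-0.57). The inhibitory ligand gene DLL3 had -0.066, not past the threshold. In the MYC, RB and p53 list 7 of 25 genes rose and 10 fell (camera adjusted p = 0.457). MYC rose by 2.11 ± 0.077 (log2, SE), from 6.37 to 8.48, while MYCN fell by 0.93 ± 0.10, from 12.53 to 11.60. MYCL (-0.055) and RB1 (-0.0073) did not pass. The p53 targets CDKN1A (-1.37), SESN1 (-1.72) and GDF15 (-0.95) fell. Other p53 targets, from the apoptosis list and named after their values were seen, were mixed. FAS (1.54) and TNFRSF10B (1.52) rose, PMAIP1 (-0.39) fell, and BAX (-0.038) and BBC3 (-0.015) did not pass. Of 38 proliferation genes, 6 rose and 11 fell (median -0.014, camera adjusted p = 0.659), with the cyclin genes CCNE2 and CCNE1 lower by -0.71 and -0.61 and CDC20 higher by 0.64. Of 20 stem-like genes, 6 rose and 8 fell, with a median of -0.072, a mean of 0.0065 and a camera adjusted p = 0.853; KLF4 fell by 1.40 and SOX11 rose by 1.22.

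Receptor and growth factor signalling genes rose in part, and MET did not pass the test. Of 37 receptor tyrosine kinase genes with HGF, 16 rose and 8 fell (median 0.17, camera adjusted p = 0.0166; adjusted p = 0.28 with an estimated correlation). AXL rose by 4.44 ± 0.20 (log2, SE), PDGFRB by 3.15 ± 0.17 and EGFR by 2.63 ± 0.15. TEK rose by 3.28 ± 0.46 and FLT1 by 2.96 ± 0.53, values that became 3.91 and 3.68 without H69M replicate 3, the lowest H69M array for both. Falls, named after their values were seen, included EPHB1 (-1.34), NTRK2 (-1.33) and EPHA7 (-1.26). MET stood at 10.01 ± 0.011 in H69 and 10.23 ± 0.24 in H69M (log2, SD, n = 3), a difference with a limma Benjamini-Hochberg adjusted p = 0.156 that became 0.0235 without H69M replicate 1 (fold change 0.34). HGF was dim in both lines (3.84 and 4.06), with a fold change of 0.23 and a limma adjusted p = 0.0423. That call was lost without H69 replicate 1 (0.121), H69 replicate 2 (0.0619), H69 replicate 3 (0.106), H69M replicate 2 (0.133) or H69M replicate 3 (0.114), and with eBayes trend (0.0793). The list's own call was lost with genes below the median level left out (camera adjusted p = 0.338).

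Genes of the MAPK, Hippo-YAP and TGF-beta lists were mostly higher in H69M. These lists share members with the mesenchymal and non-neuroendocrine lists, so their rises are in part the same result. EMP1, EPHA2, YAP1 and TGFBI are also non-neuroendocrine list members, and AXL and NT5E are also mesenchymal ones. Of 26 genes of MAPK pathway output, 21 rose and 2 fell (median 0.98, camera adjusted p = 5.29e-08; adjusted p = 0.122 with an estimated correlation), with EMP1 (3.98), the ETS factor ETV5 (3.75), EPHA2 (2.93) and HBEGF (2.78) in front. Of 27 Hippo-YAP genes, 21 rose and 4 fell (median 1.68, camera adjusted p = 6.15e-09; adjusted p = 0.281 with an estimated correlation), and the YAP targets CCN2 and ANKRD1 rose by 5.86 and 5.12. NT5E rose by 5.08. Of 29 TGF-beta and SMAD genes, 18 rose and 3 fell (median 0.56, camera adjusted p = 1.32e-06; adjusted p = 0.158 with an estimated correlation), among them the ligand gene TGFB1 (3.80) and FST (3.20), which encodes the activin antagonist follistatin. The feedback targets SMAD7 (0.053), SMAD6 (0.14) and PMEPA1 (0.21), named after their values were seen, did not pass, and BMP7 fell by 1.64. In the WNT list 14 of 32 rose and 10 fell (median 0.0090, camera adjusted p = 0.391). Its largest change was in DKK1, a secreted WNT antagonist, which rose by 5.39.

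Most measured genes of the interferon response, antigen presentation and inflammatory lists rose. Of 40 interferon response genes, 27 rose and 1 fell (median 0.45, camera adjusted p = 6.15e-09; adjusted p = 0.115 with an estimated correlation), with IFITM3 (4.66), SAMD9L (4.56) and IFITM2 (2.99) in front. Of 21 antigen presentation genes, 13 rose and 2 fell (median 0.45, camera adjusted p = 0.000311; adjusted p = 0.158 with an estimated correlation). The peptide transporter gene TAP1 rose by 3.58, CD274, which encodes PD-L1, by 2.72, the immunoproteasome gene PSMB9 by 2.18 and B2M by 0.75 ± 0.12 (log2, SE). Of 29 inflammatory cytokine and NF-kB genes, 17 rose and 3 fell (median 0.58, camera adjusted p = 4.92e-05; adjusted p = 0.158 with an estimated correlation), including the adhesion molecule ICAM1 (3.96) and the chemokine CCL2 (3.80).

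Among drug response, cell death and metabolic genes, some lists were higher in H69M and others lower. Of 36 genes of drug transport, detoxification and DNA damage, 15 rose and 8 fell (median 0.11, camera adjusted p = 0.0262; adjusted p = 0.161 with an estimated correlation). CYP1B1 rose by 4.21 and the efflux pump gene ABCC4 by 2.36, ABCC1 rose by 0.42, and ABCB1 (0.00082) and SLFN11 (0.095) did not pass. Members that fell, named after their values were seen, included ABCC5 (-0.83), MGST1 (-0.70) and XPA (-0.53). With genes below the median level left out the median of this list was -0.11 (camera adjusted p = 0.937), and its call was lost with the mean of a gene's probe sets (0.0602). Of 34 apoptosis genes, 14 rose and 6 fell (median 0.17, camera adjusted p = 0.0147; adjusted p = 0.419 with an estimated correlation), a call lost with genes below the median level left out (camera adjusted p = 0.638). CASP4 rose by 3.31 and the death ligand gene TNFSF10 by 2.94, and the survival factor BCL2 fell by 1.39 ± 0.075 (log2, SE). Other members, named after their values were seen, went against a plain shift towards cell death. The death-promoting genes BCL2L11 (-1.38) and HRK (-0.73) fell, and the apoptosis inhibitor gene BIRC2 (1.06) and the decoy receptor gene TNFRSF10D (1.55) rose. Of 29 hypoxia and glycolysis genes, 16 rose and 1 fell (median 0.23, camera adjusted p = 6.41e-05; adjusted p = 0.431 with an estimated correlation), among them the collagen prolyl hydroxylase genes P4HA2 (2.05) and P4HA1 (1.54) and the glucose transporter gene SLC2A1 (1.49). Of 18 cholesterol synthesis genes, 0 rose and 11 fell (median -0.39, camera adjusted p = 0.000546; adjusted p = 0.516 with an estimated correlation), with INSIG1 down by -0.86 and HMGCS1 by -0.78. Of 44 oxidative phosphorylation genes, 1 rose and 23 fell (median -0.23, camera adjusted p = 5e-04; adjusted p = 0.403 with an estimated correlation); ATP5F1A, a subunit of ATP synthase, fell by 0.63.

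Most developmental, housekeeping and other cell type lists did not pass the camera test. Of 27 HOX genes, 3 rose and 14 fell (median -0.26, camera adjusted p = 0.0166; adjusted p = 0.516 with an estimated correlation), with HOXB5 at -0.78 and HOXC13 at 0.95. The unfolded protein response and stress list (7 higher and 5 lower of 24, camera adjusted p = 0.625), the cancer-testis antigens (3 and 1 of 16, 0.779) and the replication-dependent histones (2 and 8 of 25, 0.278) did not pass. Of 40 cytoplasmic ribosomal protein genes, 8 were higher and 1 lower (camera adjusted p = 0.0628), and this list passed without H69 replicate 2 (0.0302) and with the arrays centred on their medians (0.0372), with eBayes trend (0.0322) and with array weights (0.0496). The marker lists of squamous and basal cells (2 higher and 4 lower of 19, camera adjusted p = 0.45), alveolar, club and ciliated cells (0 and 5 of 19, 0.147), endothelial cells (4 and 1 of 16, 0.488) and leukocytes (6 and 5 of 27, 0.921) did not pass. The leukocyte list had a median of -0.088 and a mean of 0.12. With genes below the median level left out, 3 members each remained of the leukocyte list (median 0.97, camera adjusted p = 0.0149) and of the alveolar, club and ciliated list (median -0.71, camera adjusted p = 0.0433), and both passed.

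Camera at the preset correlation called 20 of the 34 lists, 15 up and 5 down, and 0 of these calls held with an estimated correlation. Fry, which asks whether a list's genes move 1 way on balance without comparing them with other genes, called 25. Adjusted over the list alone, the counts were 27 higher and 0 lower for mesenchymal genes, 3 and 27 for neuroendocrine genes, 28 and 1 for interferon response genes, 1 and 27 for oxidative phosphorylation genes, and 4 and 1 for ribosomal protein genes.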

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

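All tests of explanations in this part were chosen after the results they bear on had been seen. The 13163 probe sets without a single gene symbol were not used in the comparison, yet 101 of them were at least 2-fold higher and 225 at least 2-fold lower in H69M at limma's Benjamini-Hochberg adjusted p threshold of 0.05. They stand here as a signal in data outside the main measurement.

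The 6 arrays can be split into 3 and 3 in 10 ways, which are too few for a share under 0.05. The real split gave 8140 genes, and 1 of the 10 splits, the real one, gave as many. The highest count of the other 9 was 0 by limma, with 124 to 519 genes at an unadjusted p under 0.05. For differences of at least 2-fold the real count was 1524, reached by 1 split, and the highest other count was 0. Every other split mixes the lines on both sides, so the difference between the lines enters the spread and lowers those counts. They do not show what a split of like arrays would give.

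At the median, neuroendocrine genes fell little (-0.48) while mesenchymal genes rose far (2.75), which a mixture of cells could give. Dilution of an unchanged H69 population by cells without neuroendocrine transcripts, as the only cause of the falls, would limit every fall to the share lost. If the neuroendocrine median gives that share, this is argued against. Of 7147 genes of the same brightness, 383 had 95% limits wholly below the lower bootstrap bound of that median (-0.71), as had 8 neuroendocrine genes. The count depends on that bound, since the neuroendocrine genes themselves spread around their median, and 43 of the 7147 genes had limits wholly below -2. Dilution by cells that carry some neuroendocrine transcripts would move the bound and was not tested. Compression of bright signals would make the brighter neuroendocrine genes fall less. Spearman's rho between H69 level and fold change across these genes, which are not independent replicates, was -0.338 (permutation p = 0.0356). The H69 level enters both quantities and dim genes have less room to fall, so a negative rho does not decide against compression. Fibroblasts in the H69M cultures stay open: 85.4% of 41 abundant fibroblast transcripts rose, above the 80% set for that test, although 30 of them are also in the mesenchymal, matrix or fibroblast lists and a change of state of the tumour cells predicts the same rise. The other 6 did not rise, among them S100A6, which fell by 0.60.

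H69M replicate 1 lay nearer to H69 than the other H69M arrays. Compression of that whole array is not decided. The trend in genes that did not pass accounted for -15.1% of the shift of the risen genes. Their median of replicate 1 minus replicate 3 was -0.17, where 0.026 was predicted. For the fallen genes the trend predicted 0.037, in the direction of the observed 0.22. Quantile normalization, part of RMA as it is usually run, would already have removed most of such a compression, so the test could hardly detect it. Of the genes that H69M replicate 2 placed at least 2-fold higher than H69, 71.0% were lower in replicate 1 than in replicate 3, and 77.1% of those placed at least 2-fold lower were higher. These shares largely restate the position on the first principal component, so they do not decide whether that array held a smaller part of the H69M state, and that stays open.

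Neighbouring genes shifted together along the chromosomes, among the 9266 protein-coding autosomal genes whose level in the higher line reached the median gene level; neighbours left out were skipped. Windows of 15 such genes with an absolute median log2 fold change above 0.5 numbered 134 (94 lower and 40 higher in H69M), against at most 29 in 1000 shuffled orders, so a chance order is argued against. Probes shared between neighbouring paralogues are argued against as well, since 125 windows remained with 1 gene per symbol root, against at most 33. Runs were built in the 8749 genes kept with 1 per symbol root, by merging windows past 0.5 in the same direction at most 15 genes apart. A run can thus include stretches under that threshold. The longest run, from SS18 to MAPK4, merged 21 windows over 51 genes with a median of -0.46, of which 36 fell and 8 rose. The longest higher run, from MAP3K13 to PPP1R2, merged 11 windows over 25 genes with a median of 0.27, of which 12 rose and 2 fell. Some genes named in other sections lie in these runs: SYT4, MEP1B and ATP5F1A in the lower one, and LPP, ETV5 and HES1 in the higher one. CDH2, which rose, also lies in the lower one. SNAP91, ADGRF5, HEY2 and EPHA7 lie in further lower runs, and SPARC and PDGFRB in a further higher run. The changes of such genes were not separated from those of their neighbours. A gain or loss of chromosome segments between the lines is a candidate explanation, as is shared regulation of neighbours, and neither was tested.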

How the results depend on the processing

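No alternative was added after the data had been seen. The counts of genes higher and lower stayed within 1.5 times under every alternative, and the 2-fold counts did except with genes below the median level left out (483 higher and 323 lower, from a smaller set of 9202 genes). More genes were lower than higher in the main counts, but this balance turned with each array centred on its median (4229 higher, 3884 lower). Quantile normalization applied again turned it too (4178 higher, 4004 lower). With a replicate block the counts were 3617 higher, 4021 lower, 1024 at least 2-fold higher and 501 at least 2-fold lower. The replicate numbers did not pair the arrays (correlations of deviations 0.021, 0.0072 and 0.0099). With 1 array left out the ranges were 3318 to 3628 higher, 3521 to 4450 lower, 999 to 1067 at least 2-fold higher and 472 to 581 at least 2-fold lower. No call changed sign except 6 with the mean of a gene's probe sets. Genes that did not pass changed sign near 0, and the cause was not tested: RB1 when centred (0.023) or quantile normalized (0.016), MYCL when quantile normalized (0.014) and ABCB1 with array weights (-0.017). The list of drug transport, detoxification and DNA damage genes also changed sign, with genes below the median level left out (-0.112, camera adjusted p = 0.937, from fewer genes). In that setting the leukocyte list passed with a median of 0.972 against -0.0881 (camera adjusted p = 0.0149), and the alveolar, club and ciliated list with -0.706 against -0.0917 (0.0433), each on the 3 members left. With 1 array left out the log2 fold change ran from -0.256 to 0.0993 for CDH1, -0.185 to 0.0122 for POU2F3, -0.0991 to 0.00669 for MYCL, -0.066 to 0.0494 for RB1, -0.041 to 0.0636 for ABCB1 and -0.0616 to 0.225 for SLFN11. RMA values give no signal over background, so folds from dim levels stay uncertain in size.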

Other observations

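All genes and gene groups in this part were chosen after their values were seen. Of the thrombin receptor family, F2R rose by 5.51 ± 0.16 (log2, SE) and F2RL2 by 5.86 ± 0.23, while F2RL3 (-0.0099) did not pass limma's Benjamini-Hochberg threshold. Of 8 receptor genes of the interleukin-6 family, 4 rose and 1 fell: IL6ST (6.60), OSMR (4.48), LIFR (3.58) and IL31RA (1.14) were higher, and CNTFR fell by 0.90. Of 9 metallothionein genes, which encode metal-binding proteins, 0 rose and 5 fell, with MT1F at -2.81, MT1G at -1.94 and MT1X at -1.47.

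Among 15 genes of an olfactory receptor cluster, 8 fell and 1 rose, with OR51F2 at -2.75, OR51E2 at -2.73 and OR51T1 at -2.68. MMP26, which lies within that cluster, fell by 1.61. Beside MYCN, its antisense gene MYCNOS fell by 1.32, whereas the neighbours NBAS and DDX1 rose by 0.24 and 0.18. The tight junction gene CLDN1 rose by 4.68.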
